A study of Homo sapiens with 72 samples.

How the data were processed

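Gene expression was measured by DRUG-seq, a barcoded sequencing method that reads the 3′ ends of polyadenylated RNA in lysates of multiwell plates. The samples were wildtype normal human dermal fibroblasts, primary cells of the skin, held for 24 hours with omaveloxolone or with the solvent DMSO in a 384-well plate. Omaveloxolone is a synthetic triterpenoid that binds KEAP1, the protein that marks the transcription factor NRF2 for degradation, and so activates NRF2. The 72 wells used here were 32 DMSO wells and 4 wells at each of 10 doses: 0.0005, 0.002, 0.005, 0.014, 0.04, 0.12, 0.37, 1.11, 3.33 and 10 µM. Treated wells lay in plate rows K and L, and DMSO wells lay in plate columns 2 and 23 across all plate rows. The protocol names 16 DMSO wells per plate, while 32 wells carried that label, and all 32 were used. Replicates were wells of the same cells. They may be technical replicates, so every p-value measures the spread between wells only.

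The deposited values were counts per gene and well, without normalization, made by the authors with kallisto and bustools on the human genome build GRCh38. The labels stated no tool versions, no annotation and no collapsing of molecular identifiers, so a count may be a read and not an RNA molecule, and intervals and floors cover counting error only. Counts were whole numbers for 23170 genes, of which 23078 matched GENCODE release 29 (Ensembl release 94) and 21289 had a symbol. Chromosomal positions come from that annotation. XIST and genes of the Y chromosome, 38 in all, were left out of every total and test. All 72 wells matched a sample, and 0 wells were left over. The sequencing depth stated for the plate amounts to a mean of 7812500 raw reads per well.

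Choices of comparison, test, gene list, named genes and alternative settings were made before the data were examined, except where an alternative is said to be added later. Each dose was compared with the 32 DMSO wells, and each of the 4 highest doses with the dose below it, in a single fit of all 72 wells by the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. The fit used TMM scaling, filterByExpr with a minimum count of 10 and robust dispersion. It left 14259 genes, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. A gene is called higher or lower only where it passed that threshold. Levels are CPM, counts scaled to a common library total, after TMM scaling, given as mean ± SD over 32 DMSO wells or 4 wells of a dose. Fold and log2 changes come from the fit, with the standard error (SE) derived from the quasi-likelihood F value. For genes with 0 counts in every well of a group, the fold is given as at least the ratio to a floor of 3 counts over the group. For genes with 1 to 3 counts, the ratio of CPM is given with an exact 95% counting interval. These bounds and intervals treat each count as a separate RNA molecule. They claim too much where several counts come from the same molecule. A linear trend on log10 dose was fitted to the treated wells, where 11624 genes passed the filter. DMSO wells of column 23 were compared with those of column 2, where 11258 genes passed.

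Gene lists, 25 in number, were tested at each dose with camera of limma 3.58.1 at a preset correlation of 0.01. Adjustment ran over all lists and doses, and each test was repeated with a correlation estimated from the data. Calls of lists printed in the text that were lost with the estimated correlation are given with that adjusted p. Members of each list were also counted with p-values adjusted over the list alone. Median changes of lists with members at 0 counts were recomputed with those members at their bound. Lists of cell type markers were counted but not tested. Of the listed genes, 8 were not among the counted genes (SOD2, THRSP, KRT5, KRT14, KRT1, TYR, SOX10 and CLDN5) and were not analysed here.

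The total count, the number of genes detected and the percent of counts on mitochondrially encoded mRNAs were compared with DMSO by exact two-sided permutation tests over all 58905 splits, adjusted over 30 tests. EC50 values, the doses of mid-range response, of NRF2 list members were fitted to log2 CPM (prior count 2) with a 4-parameter log-logistic curve, with intervals from 200 resamples of wells, in Python 3.11.15 with SciPy 1.17.1 and NumPy 2.4.6. DESeq2 1.42.0 supplied the alternative size factors and the Wald test.

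Genes were named by a fixed rule with 5 parts. HMOX1, NQO1, GCLM, GCLC, TXNRD1, SRXN1, SLC7A11, OSGIN1, NFE2L2, KEAP1 and BACH1 were always named. Other genes that the rule picked are not reported here, and the search for wells far from the others of their dose left them out. At 0.12, 1.11 and 10 µM the 10 genes with the largest rise and the 10 with the largest fall were taken. Those genes had to pass the threshold, have a symbol, reach a mean of 10 CPM over all wells and lie on the same side of the DMSO median in all 4 wells. For each list, up to 4 members with the smallest adjusted p were named, with up to 2 that moved against the majority. For 10 against 3.33 µM, 6 genes were taken in each direction, as for the steepest trends. Names outside the rule are said to be chosen after their values were seen. SRXN1 did not pass the filter on low counts.

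Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, only the 4 DMSO wells in plate rows K and L, the plate side (columns 2 to 12 or 13 to 23) as a covariate, the replicate number as a block, the 0.0005 µM wells as the reference, and leaving out each treated well. Alternatives added after the data were seen were fits without the 3.33 and 10 µM wells, fits of a dose with DMSO alone or of 8 wells of neighbouring doses, DMSO wells thinned to the depth of a dose, a trend and EC50 up to 0.37 µM, and keeping XIST and Y chromosome genes.

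The methods were checked on simulated data with 13744 genes and known changes. At 0.12 µM depth, 59% of 2-fold and 94% of 4-fold changes were recovered, and at 1.11 µM depth 64% and 92%. At 10 µM depth, 15% and 53% were recovered, with 117 false calls. Simulated EC50 values of 10, 50 and 200 nM gave medians of 9.952, 51.61 and 191.3 nM. These simulated curves only rose and were fitted over all doses. They therefore do not test EC50 fits limited to the lower doses, or genes that rise and then fall.

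Markers of other cell types were read as a check on the cells. In DMSO wells, VIM stood at 58700 CPM and DCN at 4590 CPM before TMM scaling, both abundant in fibroblasts. Of 10 fibroblast markers, 1 was lower at 0.04 µM, 2 at 0.12 µM, 9 at 0.37 µM (1 higher), 3 at 1.11 µM (3 higher), 3 at 3.33 µM (1 higher) and all 10 at 10 µM (median log2 change -2.52). At 10 µM the median of 1506 abundant genes (mean of at least 100 CPM) was also low, at -1.52, or -0.64 with DESeq2 size factors. FAP rested on 1 count there, and LUM and PDGFRA on 2 each. Of 8 pericyte and smooth muscle markers, 2 were higher at 1.11 µM and 1 at 10 µM. Of 4 keratinocyte markers tested, 1 was higher and 1 lower at 1.11 µM and 1 was lower at 3.33 and at 10 µM, and KRT10 stood at 435 CPM in DMSO. Of 3 leukocyte and macrophage markers tested, 2 were lower at 0.37 µM, 1 was higher at 1.11 and at 3.33 µM, and 1 was lower at 10 µM. The single tested marker of melanocytes was higher at 10 µM, and 1 of 2 endothelial markers was higher at 3.33 µM. Both calls rested on few counts, the endothelial one on 13 counts over the 4 wells. None of the 7 marker lists had a called member at 0.0005 to 0.014 µM.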

Results

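The transcriptome of wildtype normal human dermal fibroblasts was measured by DRUG-seq after 24 hours with omaveloxolone, a compound that frees the transcription factor NRF2 from KEAP1. The 72 wells comprised 32 DMSO wells and 4 wells at each of 10 doses from 0.0005 to 10 µM. The question of the dose series was how the fibroblast transcriptome changes over this range.

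The amount of RNA read from a well changed sharply above 0.12 µM. DMSO wells held 6657000 ± 932200 counts (mean ± SD, n = 32; range 4910790 to 8685413). The means of 4 wells at 0.0005, 0.002, 0.005, 0.014, 0.04 and 0.12 µM were 6062000, 5572000, 6858000, 6773000, 6835000 and 7759000 counts. At 0.37 µM the total was 9878000 ± 557400 counts, 1.48-fold the DMSO mean, with all 4 wells above the DMSO median. It was 1566000 ± 113800 counts at 1.11 µM, 169669 ± 31283 counts (132317 to 208739) at 3.33 µM and 30831 ± 5996 counts (25635 to 39396) at 10 µM. The last is 216-fold below DMSO. Totals at 0.37 to 10 µM differed from DMSO (exact permutation test, adjusted p = 4.64e-05 at each, from p = 1.7e-05, the smallest that 58905 splits can give). The total at 0.12 µM did not pass (exact adjusted p = 0.0725).

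Fewer genes were seen in the wells of the highest doses, and mitochondrial mRNAs took a smaller share of counts from 0.12 µM on. Genes detected numbered 13916 ± 467 in DMSO, 10739 ± 226 at 1.11 µM, 4789 ± 476 at 3.33 µM and 2428 ± 329 at 10 µM (n = 4; exact adjusted p = 4.64e-05 at each dose). Mitochondrially encoded mRNAs took 0.955 ± 0.173% of counts in DMSO, 0.449 ± 0.0876% at 0.12 µM, 0.0428 ± 0.00844% at 0.37 µM and 0.0211 ± 0.00566% at 1.11 µM (n = 4; exact adjusted p = 4.64e-05 at each dose). The share was 0.116 ± 0.0608% at 3.33 µM and 0.650 ± 0.166% at 10 µM, where the exact adjusted p was 0.00395. Of the 30 tests, 12 passed.

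**Figure D1:**
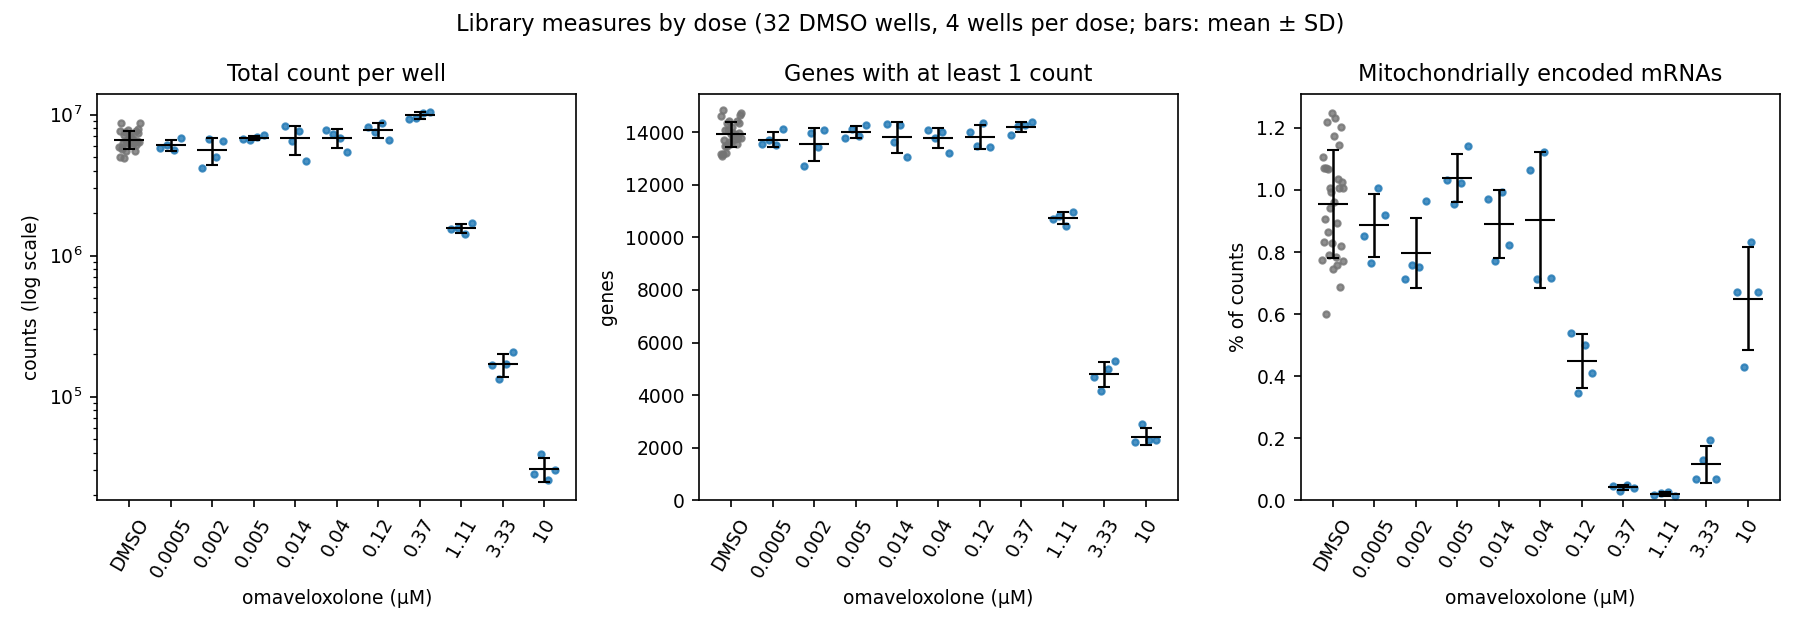
Total counts on a log scale, genes detected, and the percent of counts on mitochondrially encoded mRNAs for each well (points) with the mean and SD of each dose in µM and of DMSO. Totals fall from a mean of 9878000 at 0.37 µM to 30831 counts at 10 µM.

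The number of genes that differed from DMSO grew up to 0.37 µM and was higher at 3.33 than at 10 µM. Of 14259 genes tested, 1 was called at 0.0005 µM, 8 at 0.002 µM, 11 at 0.005 µM, 31 at 0.014 µM, 113 at 0.04 µM and 332 at 0.12 µM (187 higher, 145 lower; 234 and 477 with the DESeq2 Wald test, 448 and 462 in the fit of this dose with DMSO alone). At 0.37 µM 3533 genes were called (1593 higher, 1940 lower), at 1.11 µM 3278 (1393 higher, 1885 lower), at 3.33 µM 5734 (1048 higher, 4686 lower) and at 10 µM 5016 (478 higher, 4538 lower). The order of 0.37 and 1.11 µM is not settled. Leaving out 1 well of the dose gave 2680 to 2878 genes at 0.37 µM and 2888 to 3048 at 1.11 µM, the opposite order. A test across all doses called 8050 genes. The gene called at 0.0005 µM, ZNF860, was named after its value was seen (log2 change 5.68, adjusted p = 4.9e-05). At 0.0005 µM the DESeq2 Wald test called 0 genes higher and 12 lower, and the fit with DMSO alone 0 higher and 6 lower. With the DMSO wells of rows K and L alone, or with the replicate block, 0 genes were called. Size factors gave 1 higher gene, and the plate side as a covariate gave 3. With DESeq2 size factors in place of TMM, the median of all genes at 0.37 µM moved by 0.25 on the log2 scale, and higher genes went from 45.1% to 63.3% of those called. At 10 µM size factors moved higher genes from 9.53% to 31.6% of those called, and the median of 1506 abundant genes from -1.52 to -0.64. At this dose 8941 genes had 0 counts in all 4 wells, as did 5835 at 3.33 µM. With the DMSO wells of plate rows K and L alone, 48, 1231 and 982 genes were called at 0.12, 0.37 and 1.11 µM, and with the replicate block 47, 1209 and 796.

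**Figure D2:**
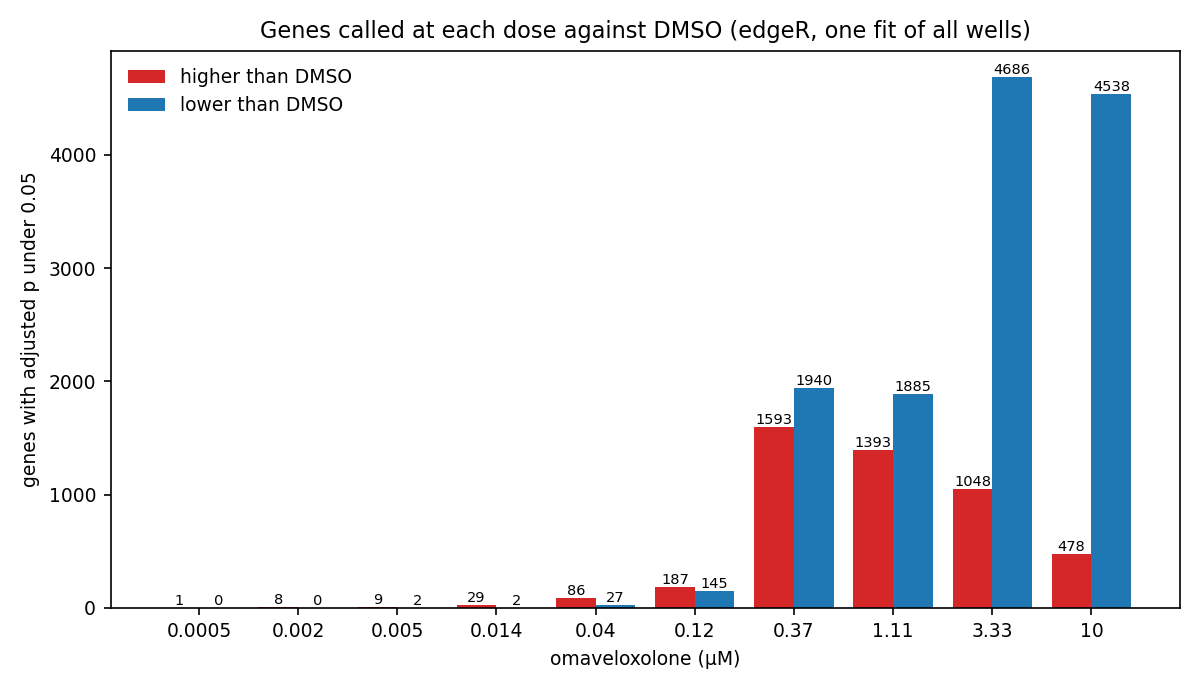
Number of genes called higher and lower than DMSO at each dose (µM; adjusted p under 0.05, n = 4 wells against 32). Bars run from 1 gene at 0.0005 µM to 5734 at 3.33 µM, and with DESeq2 size factors the higher share at 0.37 µM changes from 45.1% to 63.3%.

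At low nanomolar doses the direct targets of NRF2, the genes of the antioxidant response, rose as a group. Of 41 measured members of the NRF2 list, 0 were called at 0.0005 µM, 2 were higher at 0.002 µM, 5 at 0.005 µM, 18 at 0.014 µM, 31 at 0.04 µM and 33 at 0.12 µM, with 0 lower. Adjusted over the list alone, 2, 13, 30, 35 and 36 were higher at 0.002, 0.005, 0.014, 0.04 and 0.12 µM. The median log2 change of the list was 0.20, 0.41, 0.82, 1.37 and 1.68 at those doses (camera adjusted p = 1.08e-13 at 0.002 µM and 7.68e-178 at 0.12 µM; 1.72e-06 and 5.58e-28 with an estimated correlation). At 0.0005 µM the list was not called (adjusted p = 0.0835; median 0.09).

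NQO1 (ENSG00000181019; chromosome 16, 69706996 to 69726951), a quinone reductase used as a readout of NRF2, was the first of the genes named at every dose to be called. It stood at 419 ± 45.2 CPM in DMSO (n = 32) and 708 ± 70.0 CPM at 0.002 µM (n = 4; log2 change 0.76 ± 0.14 SE, adjusted p = 0.00413). It reached 3380 ± 133 CPM at 0.12 µM, 8.07-fold DMSO (adjusted p = 3.72e-34). The call at 0.002 µM was lost without replicate 1 (adjusted p = 0.0966) or replicate 2 (0.0613), and with the DMSO wells of rows K and L alone, the replicate block or the 0.0005 µM reference (adjusted p = 1 in each). TXNRD1 (ENSG00000198431; chromosome 12, 104215779 to 104350305), thioredoxin reductase, rose from 333 ± 41.3 to 527 ± 59.3 CPM at 0.005 µM (log2 change 0.66 ± 0.14, adjusted p = 0.0195). That call was lost with size factors, without any one of the 4 wells (0.0697 to 0.273), and with the same 3 settings as for NQO1. TXNRD1 was at 1580 ± 129 CPM at 0.12 µM (adjusted p = 1.77e-25). HMOX1 (ENSG00000100292; chromosome 22, 35380361 to 35394214), which breaks down heme, rose from 440 ± 62.9 CPM to 923 ± 37.0 CPM at 0.014 µM (adjusted p = 4.15e-06) and 9820 ± 1280 CPM at 0.12 µM, 22.3-fold DMSO.

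GCLM (ENSG00000023909; chromosome 1, 93885205 to 93909456), a subunit of the enzyme that starts glutathione synthesis, rose from 74.6 ± 19.9 to 635 ± 140 CPM at 0.12 µM (log2 change 3.09 ± 0.20, adjusted p = 5.96e-22). SLC7A11 (ENSG00000151012; chromosome 4, 138164097 to 138242349), the cystine importer, rose from 6.96 ± 5.55 to 124 ± 27.1 CPM (17.6-fold, adjusted p = 9.75e-13). OSGIN1 (ENSG00000140961; chromosome 16, 83948282 to 83966332), a growth inhibitor induced by oxidative stress, rose from 2.52 ± 2.41 to 31.4 ± 8.46 CPM (12.3-fold). GCLC (ENSG00000001084; chromosome 6, 53497341 to 53616970), the catalytic partner of GCLM, was low and variable (11.8 ± 9.08 CPM in DMSO) and was called at no dose. At 0.37 µM it stood at 22.8 ± 5.87 CPM (log2 change 0.95 ± 0.64, adjusted p = 0.298).

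On the log2 CPM scale, the mid-range dose (EC50) of this response lay in the low nanomolar range. This holds for fits of the rising part of the curve alone. Up to 0.37 µM, a range chosen after the data were seen, 24 of 39 NRF2 members gave a usable curve, all rising, with a median EC50 of 12.95 nM (quartiles 7.558 and 17.83 nM). The EC50 was 17.33 nM for NQO1 (95% interval 14.75 to 20.44), 11.09 nM for TXNRD1 (9.372 to 13.62), 38.55 nM for HMOX1 (34.45 to 43.1), 40.65 nM for GCLM (30.72 to 69.56) and 10.84 nM for SLC7A11 (7.853 to 16.93). The planned fit over all 10 doses kept 21 members, of which 2 rose, with a median of 1679 nM, because most curves went up and then down. HMOX1 gave 15.05 nM there (14.18 to 17.03), an interval apart from that up to 0.37 µM. Curves were used only with an EC50 inside the fitted doses. NQO1 wells held 2491 to 2774 CPM at 0.04 µM and 5475 to 5642 CPM at 0.37 µM. HMOX1 wells held 2551 to 3618 and 14300 to 17360 CPM. For both genes the mid-range dose in CPM, without the log2 scale, thus lay above 0.04 µM.

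The 10 genes with the largest rises at 0.12 µM were HMOX1, SLC7A11, OSGIN1, GCLM, NQO1, AFP, TRIM16L, PIR, AKR1C1 and PGD. AFP, the fetal albumin-like protein, rose from 1.99 ± 2.50 to 51.0 ± 6.14 CPM (25.7-fold, adjusted p = 2.54e-08). TRIM16L, a paralog of TRIM16, rose from 5.79 ± 3.41 to 53.8 ± 5.88 CPM. PIR rose to 244 ± 41.3 CPM (log2 change 3.11). AKR1C1, an aldo-keto reductase whose reads can be shared with its paralogs, rose from 118 ± 17.4 to 691 ± 34.2 CPM, and PGD, an NADPH-yielding enzyme of the pentose phosphate pathway, from 188 ± 24.8 to 1010 ± 105 CPM. The largest falls were in GALNT15 (a glycosyltransferase; 23.7 ± 10.6 to 0.511 ± 0.469 CPM, adjusted p = 7.69e-07), DHRS3 (a retinal reductase; 16.2-fold lower), VSIR (log2 change -3.03), H2AC6 (-2.88), BDKRB2 (a bradykinin receptor; 6.45-fold lower), TMEM35A (-2.44) and RIPOR2 (-2.43). IFIT2 (log2 change -3.34), STEAP4 (-2.78) and GALNT12 (-2.50) were also lower, but IFIT2 and GALNT12 lost their call without any one of the 4 wells, and STEAP4 without replicate 2, 3 or 4.

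In glutathione metabolism 9 of 22 members were higher and 1 lower at 0.12 µM (9 and 3 adjusted over the list alone; adjusted p = 1.66e-11), among them GSR (log2 change 1.92) and GLRX (1.43), while GPX3 fell by 1.33 on the log2 scale. The pentose phosphate list had 5 of 9 higher (adjusted p = 7.85e-23), with TALDO1 at 1.51 and ME1 at 1.68. In iron and heme handling 7 of 18 were higher, including both ferritin chains, FTL from 20000 ± 1770 to 58000 ± 5710 CPM (log2 change 1.54 ± 0.07) and FTH1 (1.10). The thioredoxin list had 4 of 11 higher (median 0.07, adjusted p = 1.4e-09), among them TXN (1.85) and PRDX1 (1.12), and 1 lower, TXNIP, an inhibitor of thioredoxin (-0.95). Proteasome subunits had 3 of 31 higher (8 adjusted over the list alone; median 0.35, adjusted p = 9.7e-10), and heat shock genes 3 of 20 (7 over the list alone; median 0.27, adjusted p = 6.47e-06).

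The list of endoplasmic reticulum chaperones was lower at 0.12 µM. HSPA5, the main chaperone of that compartment, fell from 207 ± 49.4 to 58.0 ± 23.9 CPM (log2 change -1.84 ± 0.30, adjusted p = 1.01e-05), and CALR from 419 to 188 CPM. Of 16 members of the list, 3 were lower and 0 higher (median -0.48, adjusted p = 7.39e-07). Extracellular matrix genes had 3 of 25 lower (12 over the list alone; median -0.45, adjusted p = 1.46e-07, and adjusted p = 0.128 with an estimated correlation), such as SPARC (-1.24), THBS2 (-1.17) and LUM (-1.58). Matrix and endoplasmic reticulum chaperone genes also differed between DMSO columns, by a median of 0.66 and 0.38 on the log2 scale. Of 13 mitochondrially encoded mRNAs, 4 were lower (9 over the list alone; median -0.90, adjusted p = 1.29e-07), with MT-CO3, a subunit of cytochrome oxidase, at 5160 ± 1000 CPM in DMSO and 2340 ± 294 CPM at 0.12 µM. The median of this list was -0.56 at 0.0005 µM, with 0 members called. The list was called lower there (adjusted p = 9.2e-07, and 0.0225 with an estimated correlation). The median was -0.45, -0.22, -0.42 and -0.13 at 0.002, 0.005, 0.014 and 0.04 µM, so it did not fall steadily with dose. The share of counts on these mRNAs at 0.0005 µM was 0.886%, against 0.955% in DMSO (exact permutation test, adjusted p = 0.637). With the DMSO wells of rows K and L alone, or with the replicate block, the calls at 0.12 µM of TMEM35A, RIPOR2, GLRX, GPX3, PRDX1, TXNIP, SPARC, THBS2, LUM and MT-CO3 were lost. Those of HSPA5 and CALR were lost with the first setting alone, those of H2AC6, TALDO1 and ME1 with the second alone, and those of GPX3, THBS2 and LUM also without replicate 1, 2 or 4.

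**Figure D3:**
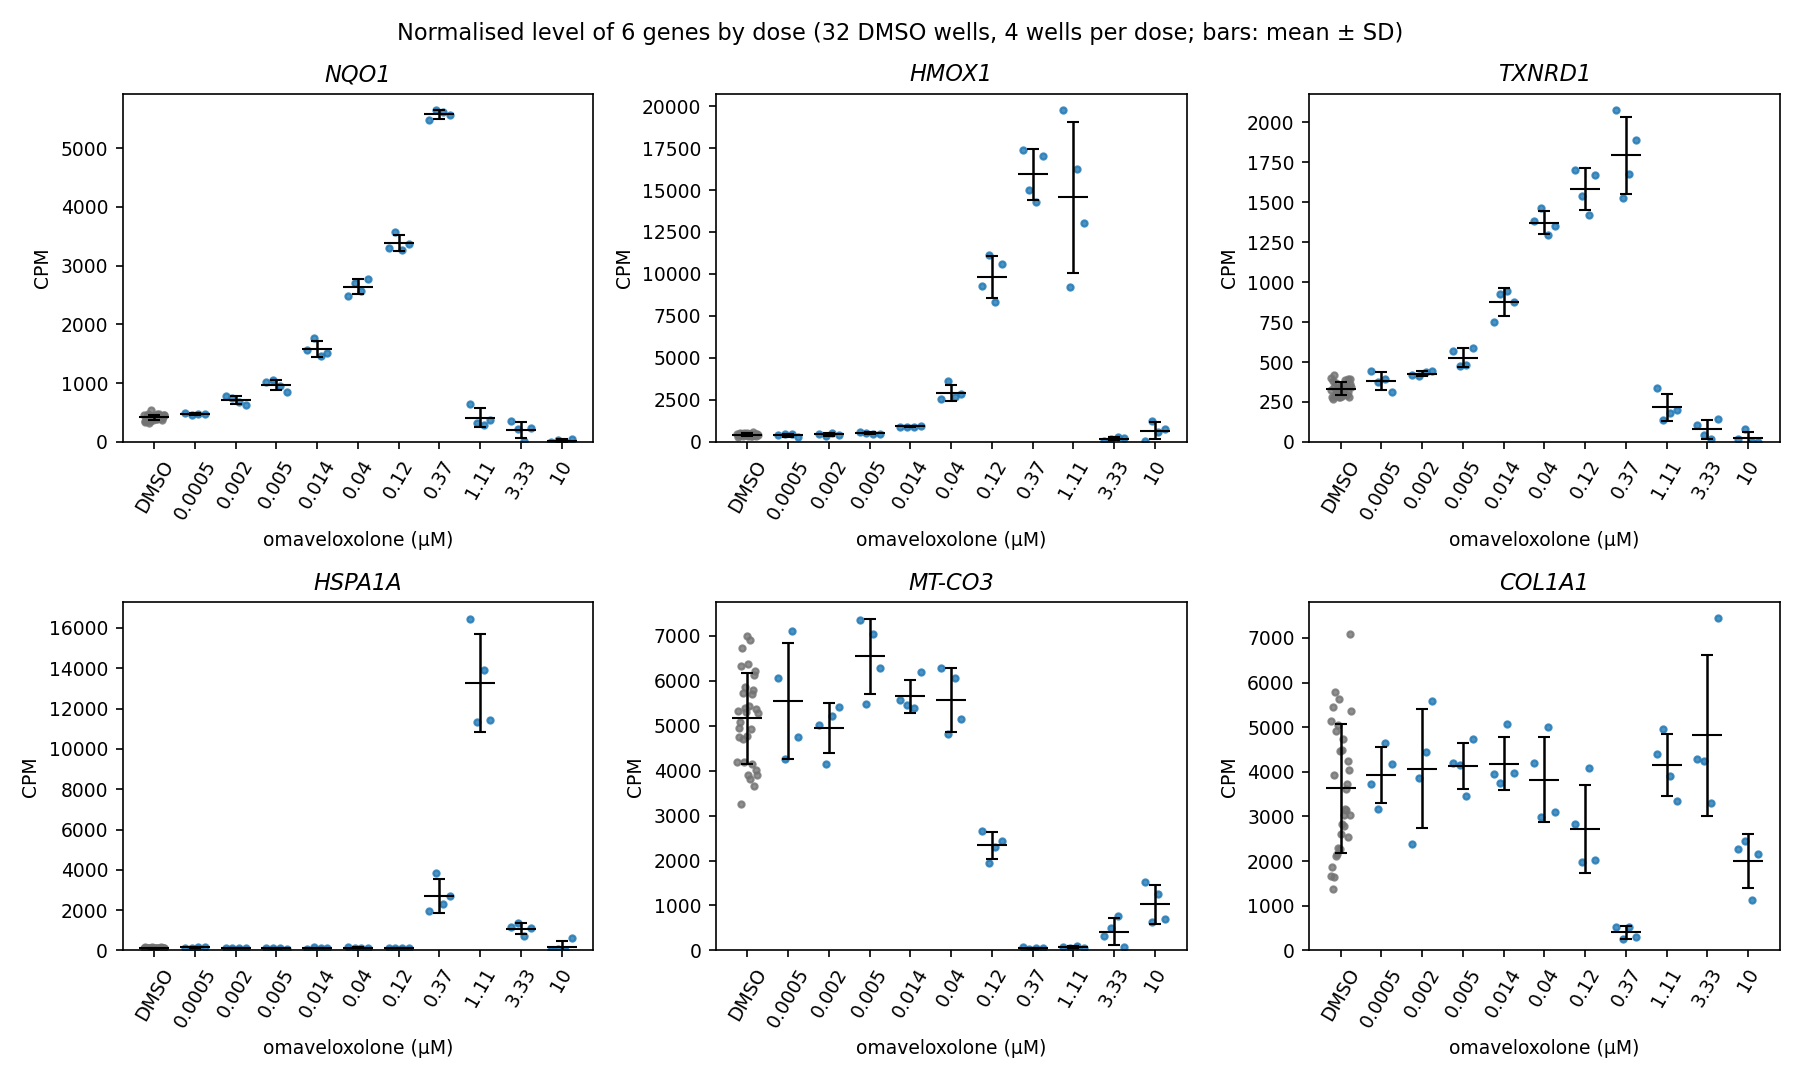
CPM on a linear scale of NQO1, HMOX1, TXNRD1, HSPA1A, MT-CO3 and COL1A1 in each well (points) with mean and SD (bars) against dose in µM, with the DMSO wells at the left. NQO1 rises from 419 CPM in DMSO to 5570 CPM at 0.37 µM and stands at 410 CPM at 1.11 µM.

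At 0.37 µM the NRF2 list had its highest median. Heat shock, proteasome and integrated stress response genes rose, and genes of cell division, sterol synthesis, fatty acid synthesis and matrix fell. NQO1 reached 5570 ± 72.6 CPM (13.3-fold DMSO, adjusted p = 1.16e-41), HMOX1 15900 ± 1510 CPM (36.2-fold), GCLM 937 ± 91.2 CPM, SLC7A11 130 ± 23.6 CPM and OSGIN1 160 ± 26.3 CPM. Of the NRF2 list 31 of 41 were higher and 1, TKT, was lower (33 and 2 over the list alone; median 1.99, adjusted p = 3.22e-47). SQSTM1, an autophagy receptor, rose from 93.9 to 1060 CPM. NFE2L2 (ENSG00000116044; chromosome 2, 177227595 to 177392697), which encodes NRF2 itself, rose from 140 ± 30.0 to 258 ± 32.5 CPM (log2 change 0.88 ± 0.19, adjusted p = 0.000187). KEAP1 (ENSG00000079999; chromosome 19, 10486120 to 10503741), its inhibitor, stood at 59.3 ± 10.9 CPM in DMSO and was not called at 0.37 µM (log2 change 0.44 ± 0.20, adjusted p = 0.0999). It was called there with size factors, by the Wald test, without the 3.33 and 10 µM wells and in the fit of this dose with DMSO alone. BACH1 (ENSG00000156273; chromosome 21, 29194071 to 29630751), a repressor of HMOX1, was at 67.8 ± 18.3 CPM in DMSO and was not called (log2 change 0.47, adjusted p = 0.161), though it was with size factors, by the Wald test and in the fit of this dose with DMSO alone. The call of NFE2L2 was lost with the DMSO wells of rows K and L alone, the replicate block and the 0.0005 µM reference.

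Redox lists held called members in both directions at 0.37 µM. Glutathione genes had 11 of 22 higher and 3 lower (adjusted p = 6.94e-07), with GLRX rising from 142 to 1220 CPM and SLC3A2, the partner of SLC7A11, from 39.2 to 480 CPM, while GPX4 (-0.99) and GPX8 (-1.25) fell. The pentose phosphate list had 4 higher and 2 lower (adjusted p = 0.0331, and adjusted p = 0.114 with an estimated correlation), a call lost also with the DMSO wells of rows K and L alone and with the replicate block. Iron and heme genes had 6 higher and 2 lower (adjusted p = 3.51e-05), with FTL at 86000 CPM. The thioredoxin list was not called (4 higher, 3 lower, adjusted p = 0.0954), but it was called as higher with size factors and without the 3.33 and 10 µM wells. Its member TXNIP fell from 309 ± 40.3 to 11.4 ± 2.70 CPM (27.1-fold, adjusted p = 3.78e-27).

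Genes of the heat shock response, the proteasome and the integrated stress response rose at 0.37 µM. Of 20 heat shock genes 18 were higher (median 1.98, adjusted p = 3.34e-36), with HSPA1A, an inducible HSP70 that shares reads with HSPA1B, going from 110 ± 20.3 to 2700 ± 827 CPM (24.6-fold) and the small chaperone CRYAB from 523 to 4660 CPM. The exception, SERPINH1, a collagen chaperone (log2 change -0.63), lost its call without any one of the 4 wells. Proteasome subunits had 26 of 31 higher and 0 lower (27 over the list alone; median 1.18, adjusted p = 4.76e-27), such as PSMB2 (261 to 800 CPM) and PSMD14 (log2 change 2.21). Of 22 targets of ATF4, the transcription factor of the integrated stress response, 14 were higher and 0 lower (median 1.59, adjusted p = 2.49e-13), such as PPP1R15A (111 to 573 CPM) and GDF15 (log2 change 3.31). Lysosome and autophagy genes had 5 of 18 higher (adjusted p = 0.000332). Targets of p53 split into 6 higher and 4 lower of 20 (adjusted p = 0.0169). CDKN1A, the inhibitor of cyclin-dependent kinases, rose from 166 to 1040 CPM and MDM2 from 81.3 to 337 CPM.

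Genes of cell division, sterol synthesis, fatty acid synthesis and matrix fell at 0.37 µM. Of 30 cell cycle genes 28 were lower (median -2.67, adjusted p = 2.29e-22), with MKI67, a marker of dividing cells, going to 1.06 ± 1.38 CPM (46.1-fold lower, log2 change -5.53 ± 0.56) and CENPF to 3.55 ± 1.96 CPM (28.3-fold lower). Cholesterol synthesis had 19 of 24 lower (median -1.93, adjusted p = 2.96e-14), such as FDPS (160 to 25.7 CPM) and FDFT1 (357 to 88.9 CPM). Fatty acid synthesis had 5 of 11 lower (7 over the list alone; adjusted p = 0.000715), with SCD, a desaturase, going from 269 to 20.7 CPM. Of 25 matrix genes 20 were lower (median -1.57, adjusted p = 5e-12), with COL1A1, a chain of the main skin collagen, going from 3630 ± 1450 to 404 ± 144 CPM (log2 change -3.17 ± 0.33) and COL6A3 from 667 to 113 CPM. The median difference of matrix genes between DMSO columns was 0.66. Ribosomal protein genes had 15 of 41 lower (median -0.21, adjusted p = 1.2e-05), a call lost with an estimated correlation (adjusted p = 0.325) and with size factors (adjusted p = 0.484).

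Mitochondrially encoded mRNAs showed the largest median fall of the lists at 0.37 µM. Of 13, 11 were lower and 0 higher (median -3.25, adjusted p = 3.03e-14, and 0.000374 with an estimated correlation). MT-CO3 fell to 49.1 ± 12.9 CPM (105-fold, adjusted p = 2.01e-32), MT-CO1 from 1770 to 95.8 CPM and MT-ND1 from 464 to 39.1 CPM. The same list differed by a median of 0.38 between DMSO columns. Beside the thioredoxin list and the metallothioneins, lists without a call at 0.37 µM were NF-kB and inflammatory genes (2 higher, 5 lower of 21; adjusted p = 0.725), interferon-stimulated genes (3 and 6 of 21; 0.348), the contractile and TGF-beta list (5 and 8 of 17; 0.578), matrix metalloproteases (2 and 5 of 13; 0.578), endoplasmic reticulum chaperones (5 and 4 of 16; 0.583), nuclear-encoded oxidative phosphorylation (3 and 9 of 46; 0.451) and apoptosis regulators (2 and 3 of 15; 0.955). Within them MMP1, a collagenase, rose from 12.4 to 214 CPM, and CCN2, a matrix-cell signal, by 3.42 on the log2 scale.

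Between 0.12 and 0.37 µM 1159 genes differed (360 higher, 799 lower), and with size factors the median of all genes moved by 0.30 and the higher share from 31.1% to 62.2%. HSPA1A rose by 4.36 ± 0.32 on the log2 scale, HSPA5 by 2.60 and NQO1 by 0.72 (adjusted p = 0.0154). MT-CO3 fell by 5.57 ± 0.29 (adjusted p = 2.51e-26), MKI67 by 4.89 and FDPS by 2.78. Without replicate 2 of 0.37 µM the number of genes was 761.

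**Figure D4:**
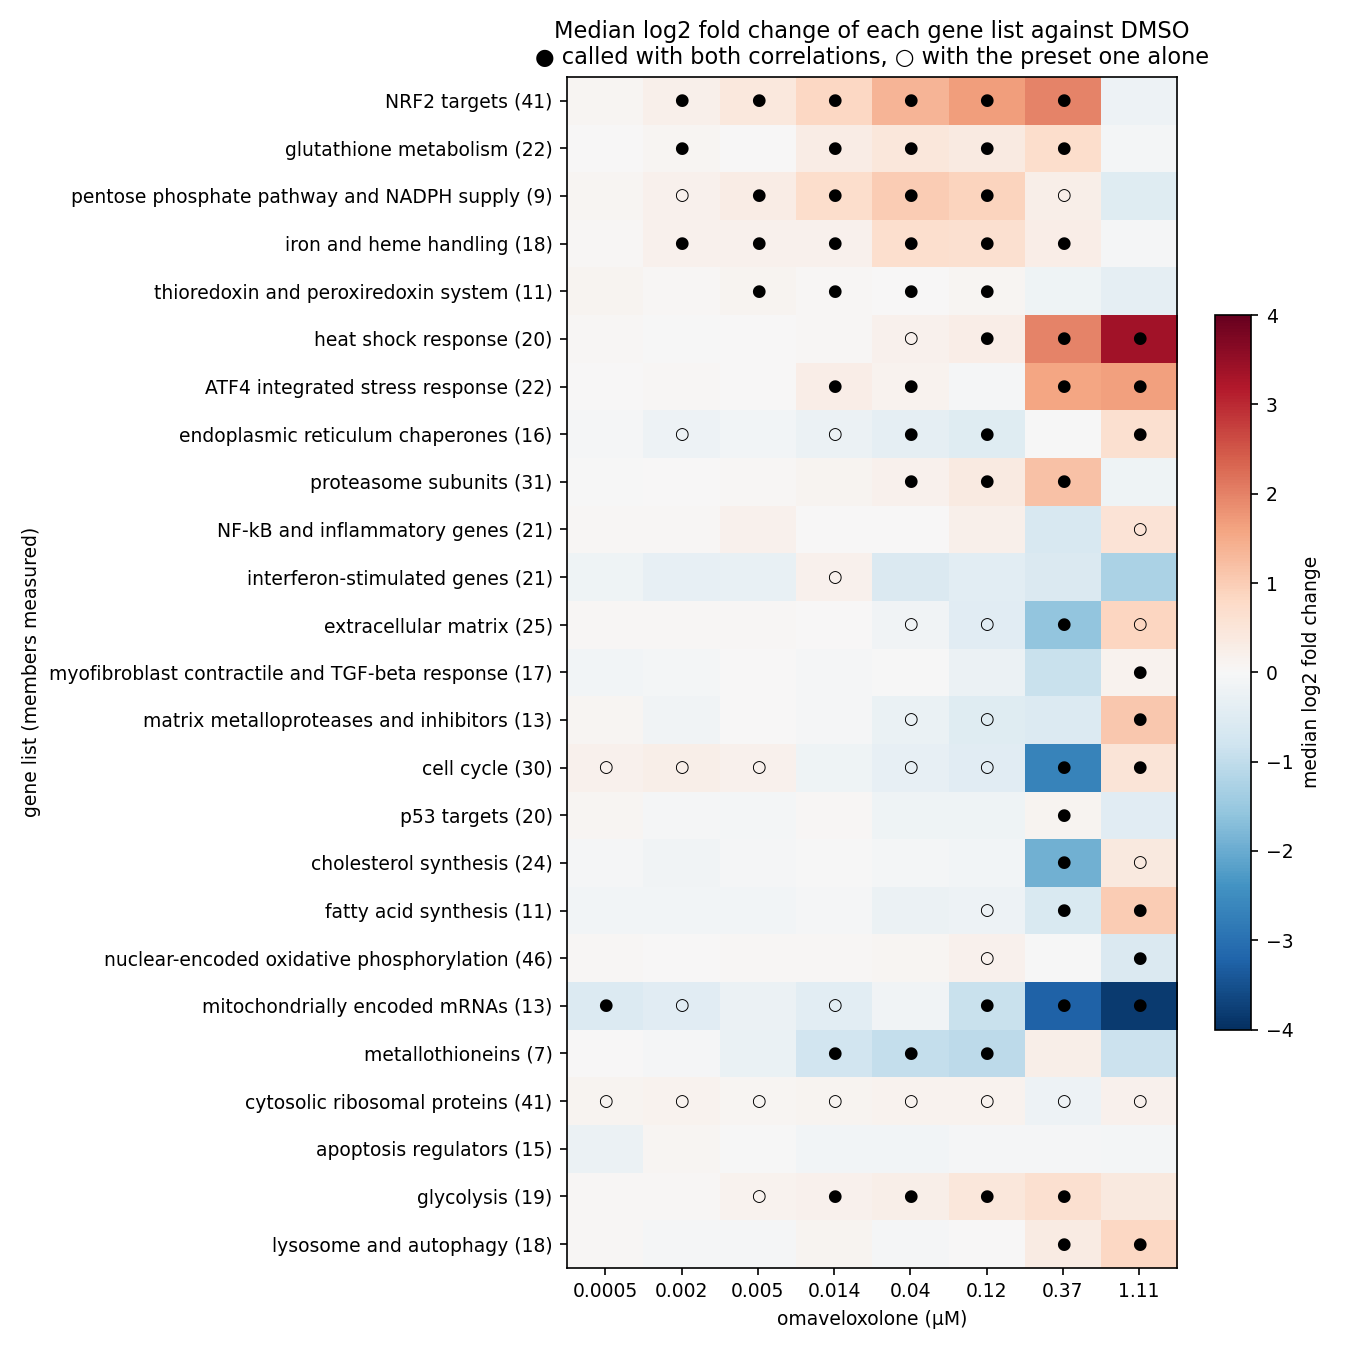
Median log2 change against DMSO of each gene list (vertical) at doses up to 1.11 µM (horizontal), with filled circles where camera called the list with both correlations and open circles where it did so with the preset correlation alone. NRF2 targets go from 0.09 at 0.0005 µM to 1.99 at 0.37 µM and -0.19 at 1.11 µM, and the call of ribosomal proteins at 0.37 µM is lost with DESeq2 size factors.

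At 1.11 µM heat shock genes dominated and most NRF2 targets stood near or below DMSO. All 20 heat shock genes were higher (median 3.35, adjusted p = 3.11e-118, and 1.14e-18 with an estimated correlation). HSPA1A reached 13300 ± 2430 CPM (121-fold DMSO, adjusted p = 6.46e-53), the co-chaperone DNAJB1 went from 55.4 ± 13.0 to 4410 ± 1030 CPM (79.6-fold), BAG3 from 53.2 to 4070 CPM and HSPD1, a mitochondrial chaperonin, from 291 to 4390 CPM. HSPA6, an HSP70 gene nearly silent without stress, went from 0.621 to 3840 ± 549 CPM (log2 change 12.52 ± 0.45). HSPA7, its close paralog with which reads can be shared, had 0 counts in DMSO and 335 ± 55.8 CPM, at least 23300-fold higher. That bound covers counting error only. The other large rises were in the early response genes FOS (2.13 ± 3.52 to 3420 ± 1260 CPM) and EGR1 (6.09 to 1310 ± 130 CPM), in HSPA1B (94.2 to 9750 CPM), in DNAJA4 (3.00 to 444 ± 130 CPM) and in RRAD (2.56 to 125 CPM).

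Among the 10 genes with the largest fitted falls at 1.11 µM, those with 0 counts in all 4 wells have only a lower bound. These bounds, and the interval for RNF103, cover counting error only, and the limits are looser if counts are reads. Genes with a mean of 1 to 5 counts in DMSO had a median variance to mean ratio of 12.9, more than counting error gives. By counting error alone, TUB was at least 24.1-fold lower than its DMSO level of 13.7 ± 7.36 CPM. AGO4 was at least 24.0-fold lower, DDX60 23.4-fold, C8orf88 21.6-fold, SAMD9 19.4-fold and ZNF469 19.3-fold. RNF103 had 1 count (DMSO 14.6 CPM; ratio 78.5, counting interval 14.1 to 3100). MT-CO2 fell from 969 ± 154 to 9.72 ± 9.37 CPM (99.9-fold) and MT-CO3 by 6.13 on the log2 scale. Outside these 10 genes COX7B, a nuclear-encoded subunit of the same oxidase, fell by 5.18.

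NRF2 targets split at 1.11 µM. Of 41 members 9 were higher and 10 lower (9 and 11 over the list alone; median -0.19, -0.13 with members at 0 counts at their bound), and the list was not called (adjusted p = 0.863). HMOX1 stood at 14600 ± 4500 CPM (33.1-fold DMSO), SQSTM1 at 233 CPM (log2 change 1.31) and SLC7A11 at 28.1 ± 13.9 CPM (2.00 ± 0.51). NQO1 was at 410 ± 159 CPM (log2 change -0.03 ± 0.16, adjusted p = 0.903), and TXNRD1 (-0.63), FTH1 (-1.07) and FTL (-0.42) were lower than DMSO. GCLM (log2 change 0.89 ± 0.25) was higher, a call lost without replicate 1 or 4, as were OSGIN1 (2.58 ± 0.55), lost without replicate 1, and NFE2L2 (0.70 ± 0.20), lost without replicate 3 or 4. Glutathione genes had 5 higher and 4 lower, GPX4 (-1.66) and GSTP1 (-1.48) among the latter, and the pentose phosphate member PGLS fell by 0.95 on the log2 scale. With the DMSO wells of rows K and L alone, or with the replicate block, the calls of TXNRD1, SLC7A11, GCLM and NFE2L2 were lost, and those of FTL and PGLS with the block.

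The direct comparison of 1.11 with 0.37 µM called 3626 genes (1720 higher, 1906 lower). Size factors moved the median of all genes by -0.20 and the higher share from 47.4% to 37.0%. NQO1 fell by 3.76 ± 0.23 on the log2 scale (adjusted p = 8.66e-23), TXNRD1 by 3.06, GCLM by 2.76, FTL by 2.53 ± 0.11 and SLC7A11 by 2.22, while HMOX1 was not called (-0.13 ± 0.23, adjusted p = 0.721). Genes that lay below DMSO at 0.37 µM were higher at 1.11 than at 0.37 µM in several lists. MKI67 rose by 5.92 ± 0.60 (adjusted p = 1.13e-12), UBE2C by 6.17, COL1A1 by 3.36 ± 0.37, FDPS by 2.94 ± 0.21 and SCD by 4.73 ± 0.29. DNAJB1 rose by 4.68 ± 0.29 and FOS by 6.94, and CDKN1A fell by 1.67. MT-CO3 was not called (0.58 ± 0.26, adjusted p = 0.0882).

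The ATF4, endoplasmic reticulum chaperone and metalloprotease lists were higher than DMSO at 1.11 µM with both correlations. Of 22 ATF4 targets 14 were higher and 2 lower (median 1.63, adjusted p = 1.92e-15), with DDIT3, a stress transcription factor, going from 29.0 to 631 ± 23.2 CPM and SESN2 from 29.4 to 236 CPM, while XPOT and PHGDH fell by 1.32 and 1.12 (calls lost with the 0.0005 µM reference and, for PHGDH, without replicate 3). Endoplasmic reticulum chaperones had 9 of 16 higher (median 0.64, adjusted p = 8.16e-06), with HSPA5 at 659 ± 78.3 CPM. Matrix genes had 16 of 25 higher and 2 lower (adjusted p = 3.41e-10, and adjusted p = 0.0584 with an estimated correlation), such as FN1, fibronectin (1410 to 4090 CPM), and THBS1 (125 to 694 CPM). COL3A1 fell by 1.53, and COL1A1 at 4150 CPM was not called (0.19, adjusted p = 0.596). Matrix metalloproteases had 8 of 13 higher (median 1.09, adjusted p = 1.08e-09), such as MMP3 (267 to 1480 CPM), beside a median difference of 0.51 between DMSO columns. The contractile and TGF-beta list had 6 higher and 2 lower of 17 (adjusted p = 0.000702), with CCN1 going from 208 to 3840 CPM.

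Cell cycle genes had 11 of 30 higher at 1.11 µM (median 0.52, adjusted p = 3.51e-05), such as UBE2C at 464 ± 169 CPM, a call lost with the replicate block, while MKI67 at 65.7 CPM was not called (0.40, adjusted p = 0.411). Fatty acid synthesis had 7 of 11 higher (adjusted p = 2.27e-05), with SCD at 549 CPM, also lost with the replicate block. Cholesterol synthesis had 4 of 24 higher and 1 lower (adjusted p = 0.00359, and adjusted p = 0.0575 with an estimated correlation). Lysosome genes had 8 of 18 higher (adjusted p = 3.22e-08), such as CTSB (1.64). Nuclear-encoded oxidative phosphorylation genes had 25 of 46 lower and 1 higher (median -0.59, adjusted p = 1.89e-07), such as NDUFB7 (98.7 to 24.1 CPM). Of 13 mitochondrially encoded mRNAs 10 were lower (median -3.83, adjusted p = 1.48e-21). NF-kB and inflammatory genes had 7 of 21 higher and 3 lower (adjusted p = 0.0423, and adjusted p = 0.0528 with an estimated correlation), a call lost in every alternative, with adjusted p from 0.051 to 0.17. Ribosomal protein genes had 12 higher and 7 lower of 41 (adjusted p = 0.00864, and adjusted p = 0.564 with an estimated correlation). Interferon-stimulated genes (0 higher, 6 lower of 21; adjusted p = 0.0501), proteasome subunits (2 and 4 of 31), p53 targets (6 and 8 of 20; 0.792) and apoptosis regulators (3 and 2 of 15; 0.583) were not called.

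At 3.33 µM, with a mean of 169669 counts per well, most called genes were lower than DMSO. NRF2 targets had 3 higher and 19 lower of 41 (median -1.21, -0.67 with members at 0 counts at their bound; adjusted p = 0.00475, and adjusted p = 0.0706 with an estimated correlation). HMOX1 fell to 189 ± 79.3 CPM (log2 change -1.21 ± 0.23). From 1.11 to 3.33 µM it fell by 6.26 ± 0.31 on the log2 scale (adjusted p = 7.56e-29), HSPA1A by 3.61 and DNAJB1 by 4.64, among 4957 genes called (1016 higher, 3941 lower). Ribosomal protein genes had 36 of 41 higher than DMSO and 1 lower (median 0.84, adjusted p = 4.79e-99, and 4.37e-07 with an estimated correlation). Thioredoxin (1 higher, 8 lower of 11), proteasome (2 and 13 of 31), both lost with the replicate block, and mitochondrially encoded genes (1 and 9 of 13; median -3.10, -2.61 with bounds) were lower with both correlations. Iron and heme genes (0 and 12 of 18) were lower with the preset correlation alone (adjusted p = 0.0823 with an estimated correlation). Heat shock (adjusted p = 0.181 with an estimated correlation), matrix metalloprotease (0.129) and lysosome lists (0.175) were called as higher with the preset correlation alone. Their signs were mixed, with medians of -0.17, 0.16 and -0.09 (0.12 with bounds for the last) and a mean of -0.79 for the metalloproteases.

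At 10 µM, with a mean of 30831 counts per well, 12 lists were lower than DMSO and 0 higher. With an estimated correlation 5 of them were called: NRF2 targets (1 higher, 19 lower; median -2.24, -0.94 with bounds), the pentose phosphate list (0 and 7 of 9; -3.02, -1.56 with bounds), the thioredoxin list (0 and 8 of 11), proteasome subunits (0 and 16 of 31; -2.12, -1.09 with bounds) and oxidative phosphorylation (2 and 29 of 46; -1.36, -1.35 with bounds). With size factors NRF2 targets (adjusted p = 0.0557), proteasome subunits (0.447) and oxidative phosphorylation (0.28) lost their call. The other 7 were not called with an estimated correlation: iron and heme (adjusted p = 0.145), heat shock (0.137), endoplasmic reticulum chaperones (0.126), matrix (0.459), fatty acid synthesis (0.175), ribosomal proteins (0.175) and glycolysis (0.055). Heat shock, matrix and ribosomal protein genes were lower in the TMM fit and went the other way with size factors (adjusted p = 0.61, 0.951 and 4.57e-30). The 10 genes with the largest fitted falls had 0 counts in all 4 wells, so only a lower bound is given. These bounds cover counting error only and are looser if counts are reads. DDX5, an RNA helicase at 501 ± 52.1 CPM in DMSO, was at least 42.8-fold lower, RTRAF 32.6-fold, MYOF 25.8-fold, ELAVL1 25.3-fold, SFPQ 24.1-fold, SEC31A 22.2-fold, RAB11A 21.3-fold, IFI16 21.3-fold, CAPZA2 21.0-fold and HNRNPM 19.1-fold. The largest rises rested on few counts over 4 wells: SPINT2 (17 counts; 8.73 ± 1.66 to 68.4 ± 30.0 CPM), SLC2A4 (88 counts; 71.0 to 337 ± 98.4 CPM), OPRM1 (log2 change 2.31), CFAP251 (2.29), HEPACAM (2.14), KCNJ2 (2.13), SUPT20HL2 (2.09), PRELP (2.04), RPS6KB2 (1.91) and BAP1 (1.89). HMOX1 at 664 ± 500 CPM was called higher (0.62 ± 0.21, adjusted p = 0.0157), a call lost without replicate 2 (adjusted p = 0.785) or replicate 4 (0.0851), with the DMSO wells of rows K and L alone (0.0665) and with the replicate block (0.119).

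Between 3.33 and 10 µM 2974 genes differed (796 higher, 2178 lower) and the higher share moved from 26.8% to 58.4% with size factors. A fit of those 8 wells alone called 15. YWHAE, a 14-3-3 protein, rose to 436 ± 126 CPM (log2 change 2.46 ± 0.26), IFNGR2 from 6.09 to 70.9 CPM, PRPF6 from 13.5 to 138 CPM, and PTPN23 and SH2B1 rose by 3.02 and 2.69 on the log2 scale, the last call being lost without replicate 1 of 10 µM. ARID5A had 2 counts at 3.33 µM and 97.8 CPM at 10 µM (ratio 40.8, counting interval 11.3 to 336). ID1, an inhibitor of differentiation factors, had 0 counts at 10 µM, at least 39.0-fold below its 456 ± 274 CPM at 3.33 µM, as did RBMX (27.6-fold), RTRAF (27.4-fold), APBB1IP (23.4-fold), SEC31A (19.8-fold) and HSPA6 (18.8-fold). The call of HSPA6 was lost with size factors, with the Wald test and without any one of the 4 wells of 10 µM. The bounds of these genes and the interval for ARID5A cover counting error only.

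A linear trend on log10 dose over the treated wells was called for 1153 of 11624 genes (255 rising, 898 falling). The split depended on the scaling and the range of doses, with 414 rising and 360 falling with size factors and 1368 and 1212 up to 0.37 µM. The steepest rises per 10-fold dose were in FOS (2.53 ± 0.53, adjusted p = 0.00299), EGR1 (2.01 ± 0.34), DNAJA4 (1.78), MLLT11 (1.70), HSPA1A (1.63 ± 0.29) and SPP1 (1.60). The steepest falls were in DDX60 (-1.20), MTND1P23 (-1.16), GALNT15 (-1.03), MT-CO3 (-0.97 ± 0.20), POLR2J3 (-0.94) and MTATP6P1 (-0.92), of which MTND1P23 and MTATP6P1 are pseudogenes that can share reads with mitochondrial mRNAs. The trends of FOS, DNAJA4, MT-CO3, POLR2J3 and MTATP6P1 were not called in a fit up to 0.37 µM, and that of POLR2J3 not with size factors. A straight line misses genes that rise and then fall, such as NQO1. The doses also lay in column order on each plate side, so a trend on dose cannot be told apart from a gradient over columns within a side.

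DMSO wells differed between plate columns, which sets a background for the comparisons with treated wells. Column 23 had 371 genes higher and 316 lower than column 2 among 11258 tested (n = 16 wells each). Matrix genes had 18 of 25 higher in column 23 (median 0.66, adjusted p = 7.39e-46, and 0.000322 with an estimated correlation), with COL6A3 at 0.92 and COL6A2 at 0.79 on the log2 scale, both chosen after their values were seen. Mitochondrially encoded mRNAs had 10 higher and 1 lower (median 0.38, adjusted p = 6.17e-12), and ribosomal protein genes had 28 of 41 lower (median -0.14, adjusted p = 4.73e-21, and adjusted p = 0.0734 with an estimated correlation). Fatty acid synthesis (median 0.29), lysosome genes (0.30), endoplasmic reticulum chaperones (0.38) and metalloproteases (0.51) were also higher in column 23, and nuclear-encoded oxidative phosphorylation (-0.13) and proteasome subunits (-0.10) lower, each with both correlations. Cholesterol synthesis (0.19; adjusted p = 0.163 with an estimated correlation) and interferon-stimulated genes (-0.38; 0.312) were called with the preset correlation alone. NRF2 targets were not called (2 higher, 3 lower of 38; median -0.06, adjusted p = 0.135).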

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

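Wells that lay far from the other 3 of their dose were sought among 125 sets of 4 wells, covering the library measures and the genes named at every dose, with a rule chosen before the data were examined. Chance alone sets a well apart in about 5% of such sets, and 10 were found. No explanation was tested for any of them, technical or biological.

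Below 1.11 µM the wells stood apart by small amounts on the log2 CPM scale. For KEAP1 at 0.005 µM, replicate 2 was at 5.95 and the others between 6.19 and 6.22. For OSGIN1 at 0.37 µM, replicate 2 was at 7.64 and the others between 7.17 and 7.23.

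At 1.11 µM, SLC7A11 was at 3.09 in replicate 4 and between 4.99 and 5.35 in the others. At 3.33 µM, NQO1 was at 4.11 in replicate 3 and between 7.75 and 8.45 in the others.

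The remaining values came from wells with few counts. At 3.33 µM, GCLC (3.75) was seen in replicate 2 only, and the other 3 wells stood at -1.48, the value of a count of 0. At 10 µM the same held for GCLM in replicate 3 (6.14), SLC7A11 in replicate 4 (5.57), OSGIN1 in replicate 1 (4.06) and BACH1 in replicate 2 (3.79). Replicate 2 of 10 µM had 2917 genes detected, against 2205 to 2305 in the others.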

How the results depend on the processing

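Alternatives that were added after the data were seen are the fits without the 3.33 and 10 µM wells, the fits of a dose with DMSO alone or of 8 wells, thinning, the ranges up to 0.37 µM, and keeping XIST and Y chromosome genes. Of 286 values of 29 counts and summaries under alternatives, 204 stayed near the reported value and 82 moved further. Near means within 1.5 times for counts. For the median EC50 it means closer on the log10 scale than the SD over the members kept (0.6869). Of 850 list tests, 769 kept direction and side of the threshold, 69 lost the call, 8 gained it and 4 turned direction. Of 6595 gene tests, 6002 kept both, 576 lost the call, 16 gained it and 1 turned. The depth of the 3.33 and 10 µM wells limits every statement on genes lower there. The replicate numbers were not taken to pair wells: same-number wells of different doses had correlations from -0.37 to 0.46 (mean -0.01; 26 of 180 pairs over 0.1; 1506 genes, after removing group means). Replicate 1 lay on the left plate side at 0.0005 to 0.005 µM and on the right from 0.014 µM on, so the replicate block, run as planned with 4 DMSO wells, mixes the plate sides. Where no cause is named, the cause was not tested.

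Settings that leave 4 DMSO wells have less power by construction. With only DMSO wells of rows K and L, the genes called at 0.0005 to 1.11 µM numbered 0, 0, 0, 4, 18, 48, 1231 and 982, the lists called at 0.002 and 10 µM numbered 5 and 6, and 0 library measures passed. That 0 says nothing on the library measures. Splits of 4 against 4 wells are too few for the exact test to pass after adjustment unless most of the tests do. With the replicate block, 0, 0, 1, 4, 17, 47, 1209, 796 and 3707 genes were called at 0.0005 to 3.33 µM, 2354 between 0.37 and 1.11 µM, 489 between 0.12 and 0.37 µM and 5021 at any dose. The lists called with it at 0.0005 and 3.33 µM both numbered 5. With the 0.0005 µM wells as the reference, 0, 0, 9, 31, 115, 2161 and 1745 genes were called at 0.002 to 1.11 µM.

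The DESeq2 Wald test called 12 genes at 0.0005 µM, 28 at 0.005 µM, 67 at 0.014 µM, 254 at 0.04 µM, 711 at 0.12 µM, 3160 at 10 µM and 2252 between 0.12 and 0.37 µM. DESeq2 size factors gave 2957 genes and 5 lists at 10 µM. Without a filter, 185, 153, 204, 163 and 289 genes were called at 0.0005 to 0.04 µM, 2917 for the trend and 2212 between DMSO columns. With the plate side as a covariate, 3 genes were called at 0.0005 µM.

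Leaving the 3.33 and 10 µM wells out gave 13, 17, 56, 242 and 707 genes at 0.002 to 0.12 µM, 1893 between 0.12 and 0.37 µM and 5179 at any dose. Fits of a dose with DMSO alone gave 6, 19, 37, 89, 322 and 910 at 0.0005 to 0.12 µM. Fits of 8 wells gave 15 between 3.33 and 10 µM, 485 between 1.11 and 3.33 µM, 1828 between 0.37 and 1.11 µM and 2249 between 0.12 and 0.37 µM. With DMSO wells thinned to the depth of the dose, 2243 genes were called at 3.33 µM and 378 at 10 µM, where far fewer genes passed the filter. Up to 0.37 µM the trend called 2580 genes and the median EC50 was 12.95 nM.

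With an estimated correlation, 1, 3, 4, 11, 4 and 5 lists were called at 0.0005, 0.002, 0.005, 0.12, 3.33 and 10 µM. The lists that turned were the matrix list at 0.014 µM with DMSO wells of rows K and L (adjusted p = 0.0421) and, at 10 µM with size factors, the heat shock (0.61), matrix (0.951) and ribosomal protein lists (4.57e-30). The gene that turned was CXCL8 at 1.11 µM, whose log2 change ran from 0 without replicate 4, the only well with counts, to 8.42 without replicate 1.

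Leaving out 1 treated well gave 2 to 8 genes at 0.0005 µM, 204 to 292 at 0.12 µM (204 without replicate 2) and 761 to 933 between 0.12 and 0.37 µM (761 without replicate 2 of 0.37 µM). At the other doses and comparisons, the counts stayed within 1.5 times those reported.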

Other observations

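Tests of the NRF2 pattern, apart from that of plate columns, and the other splits of the wells were chosen before the values they measure were seen, and the tests of plate columns, of the mitochondrial pattern, of lost genes at 3.33 and 10 µM and of the spread of low counts only after.

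Of the metallothioneins, which bind zinc and copper, 3 of 7 were lower and 0 higher at 0.12 µM (median log2 change -1.05, adjusted p = 0.000118, and 0.0036 with an estimated correlation), with MT2A going from 264 to 114 CPM. At 0.37 µM 3 were higher and 1 lower and the list was not called (adjusted p = 0.143), with MT2A at 832 CPM and MT1G at 18.4 ± 17.9 CPM. Reads can be shared between these paralogs. Glycolysis genes rose at 0.12 µM (4 of 19 higher, 8 over the list alone; median 0.45, adjusted p = 5.27e-09), such as PFKP (log2 change 1.00) and GAPDH (0.44), and at 0.37 µM 10 were higher and 2 lower (adjusted p = 2.44e-05), with the glucose transporter SLC2A3 at 2.33.

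CXCL8, a chemokine that draws neutrophils, had 0 counts in 32 DMSO wells, 74 counts at 0.12 µM (at least 167-fold higher, adjusted p = 2.77e-06, lost with the Wald test) and 77.1 ± 5.47 CPM from 2886 counts at 0.37 µM (at least 5350-fold higher, adjusted p = 3.92e-13). At 1.11 µM its 33 counts lay in 1 well. The bounds for CXCL8 cover counting error only. IFIT1, an interferon-induced gene, fell by 4.84 on the log2 scale at 0.37 µM. AFP reached 177 ± 15.5 CPM at 0.37 µM, 89.1-fold DMSO, and fell by 5.07 from there to 1.11 µM.

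Counts of mitochondrially encoded mRNAs per well, without scaling, were 64300 ± 17300 in DMSO (n = 32), 35300 ± 10100 at 0.12 µM, 4240 ± 939 at 0.37 µM, 327 ± 71.6 at 1.11 µM, 192 ± 98.9 at 3.33 µM and 193 ± 18.9 at 10 µM (n = 4 each). The ratio of 10 to 3.33 µM was 1.01 (exact permutation p = 1 over 70 splits), while that of the total counts was 0.182.

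NRF2 targets were lower at 1.11 than at 0.37 µM, a fall that runs against the dose. Lower depth is argued against by thinning the 0.37 µM wells to the mean total of the 1.11 µM wells: 30 of 40 members were still higher than DMSO, against 32 before. A scaling shift is argued against by the median of the list, which lay -2.13 from that of abundant genes (0 members higher, 30 lower of 41). A gradient over plate columns is argued against by the 1.11 µM wells of column 15, where the median of the list lay -2.10 from the 0.37 µM wells of column 6 (36 of 41 members lower), close to the -2.12 between columns 5 and 6. Between the DMSO columns the median of the list was -0.06. A response of the cells to the dose may account for the fall, as a hypothesis found on these data. Loss of cells, decay of RNA and effects of single columns, since each dose had its own, were not tested and stay open.

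Mitochondrially encoded mRNAs were lower at 0.37 µM than in DMSO. A scaling shift is argued against by a median that lay -3.15 from that of abundant genes, and lower depth by totals that were 1.48 times those of DMSO. Plate position is argued against as the whole cause, since 9 of 13 mRNAs were also called lower against the 0.0005 µM wells of the same plate rows, though the list differed between DMSO columns (median 0.38) and was lower than DMSO at 0.0005 µM (median -0.56, adjusted p = 9.2e-07, and 0.0225 with an estimated correlation). An effect of the dose on mitochondrial transcripts may be the cause, as a hypothesis, and poorer capture of these mRNAs was not tested.

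Most genes called at 3.33 and 10 µM were lower than DMSO. When DMSO wells were thinned to the depth of 10 µM, 4.69% of the lower calls stayed (211 of 4500), but the filter left only 490 of the 4500 to be tested. Of these 490, 43.1% stayed, and their median log2 change went from -1.55 to -0.59. Thinned to the depth of 3.33 µM, 30.6% stayed (1467 of 4788), with 2055 still tested, of which 71.4% stayed and whose median went from -1.97 to -1.52. These shares lie between the bounds set for either reading, or rest on genes that could no longer be tested, so low depth and loss of transcripts cannot be told apart at either dose. Thinning draws single reads and so misses the loss of whole molecules with all their copies. At 1.11 µM 88.5% stayed (1949 of 2202), with 2089 still tested.

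A count may stand for a read and not for an RNA molecule, as a hypothesis. Among 2812 genes with a mean of 1 to 5 counts in DMSO, the median ratio of variance to mean was 12.9, and 63.1% of wells were at 0 against 14.5% in a Poisson model. Differences between wells of other kinds were not separated from it.

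Other splits of the same wells were counted for each number of genes, with the real split counted in. In fits of a dose with DMSO wells alone, 1 of 21 splits, the real one, gave as many genes at each dose, the smallest share that 21 splits can give. So few splits at each of 10 doses cannot exclude a random grouping, and show only that no other split drawn gave as many genes. The splits say nothing on the directions, which depended on the fit up to 0.12 µM. At 0.0005, 0.002, 0.005, 0.014, 0.04 and 0.12 µM, 0, 4, 11, 46, 163 and 448 genes were higher and 6, 15, 26, 43, 159 and 462 lower in fits with DMSO alone, against 1, 8, 9, 29, 86 and 187 higher and 0, 0, 2, 2, 27 and 145 lower in the fit of all wells. With the DMSO wells of rows K and L alone 0, 0, 0, 4, 18 and 48 were called at these doses, and with the replicate block 0, 0, 1, 4, 17 and 47. The real and the highest other numbers were 6 and 2 at 0.0005 µM, 19 and 1 at 0.002 µM, 37 and 3 at 0.005 µM, 89 and 3 at 0.014 µM, 322 and 1 at 0.04 µM, 910 and 2 at 0.12 µM, 4795 and 110 at 0.37 µM, 3834 and 2 at 1.11 µM, 5867 and 43 at 3.33 µM, and 5014 and 40 at 10 µM. For any dose they were 8050 and 293, and for DMSO columns 687 and 1. In fits of 8 wells of neighbouring doses, with 35 splits, they were 15 and 1 for 10 against 3.33 µM, 485 and 0 for 3.33 against 1.11 µM, 1828 and 0 for 1.11 against 0.37 µM, and 2249 and 0 for 0.37 against 0.12 µM.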
